A study of Caenorhabditis elegans with 2 samples.

How the data were processed

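Chromatin from late embryos of strain OP120, carrying an eGFP-tagged ceh-30 transgene, was immunoprecipitated and sequenced in 2 biological replicates, numbered as the labels number them. The labels name ceh-30 as the antibody and describe the assay as directed at the eGFP-tagged protein. A control library is named by the labels and was not analysed here. Both replicates belong to 1 group, so no test compares groups, and p-values describe peaks or genes within the lists, not differences between animals.

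The authors made 4 peak lists per genome assembly, ce11 and ce10. Per the deposited descriptions of the files, relaxed lists of peaks and background were called on each replicate and on the pooled replicates, each with a control alignment, and the optimal list was derived from these by the irreproducible discovery rate (IDR) procedure. The peak caller, the aligner and the IDR threshold are not given in the sources used here. The deposited lists give a signal value for each peak, which is the authors' own peak height, is never negative and whose scale depends on the library or pool it was called on, so it was used to rank and filter peaks within a list. The deposited lists also give a significance score for each peak. It was below 0 for 27058 of the 30000 pooled peaks, so it was read as a score and not as a q-value, and 247 of the optimal peaks shared its highest value. It was not used in any test. The optimal list equals the 545 peaks of highest signal in the pooled list. The replicate 1 and pooled lists both end at 30000 peaks. Peaks have a near-constant width in each list, 344 bp for the optimal and pooled lists, 350 bp for replicate 1 and 330 bp for replicate 2 on ce11. No list holds read counts, so depth per sample is unknown and exact intervals on shares cover the counting of peaks or genes only.

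The ce11 lists were set against the Ensembl release 115 annotation of WBcel235, which uses the same coordinates, and the ce10 lists were used only for chromosome counts and replicate correlations. On ce10 the optimal list held 540 peaks, and 538 could be paired on the same chromosome with a ce11 peak of signal within 1%. Coordinates are 1-based on ce11. All 19973 protein-coding genes of the 6 nuclear chromosomes were the background for gene lists. A gene is called bound if a summit lay in its promoter window, defined below, which does not by itself show binding by CEH-30. Gene names that stand for several genes were counted by gene.

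Chromosome counts were compared with each chromosome's share of the nuclear bases by exact binomial tests. Summits in promoter windows (1000 bp upstream to 500 bp downstream of a 5′ end), exons, introns and intergenic sequence were compared with 1000 shuffles within chromosomes, two-sided. Gene lists were compared by Fisher's exact test, and homeodomain words by exact McNemar tests of the window within 50 bp of the summit against windows of the same length 300 bp to either side. All words of 6 bases were compared by Fisher's exact test. Peaks of the replicates were matched to optimal peaks by at least 1 bp of overlap, taking the strongest, and correlations were given with Fisher z intervals and tested with 100000 pairings (10000 for the relaxed list). Transgene loci were compared with 10000 random windows, one-sided. Adjusted p-values are Benjamini-Hochberg within the chromosomes, the lists or the words, at a threshold of 0.05.

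The tests, gene lists, alternatives and the rule for named items were fixed before the data were examined. Named items were the 15 optimal peaks of highest signal, up to 4 bound members of each list by signal, ceh-30, egl-1 and unc-119, and of the words of 6 bases the 5 with the smallest p among those higher at summits and the 2 among those lower. Alternatives were the 272 optimal peaks of highest signal, the 545 strongest peaks of each replicate alone, the ce10 lists, other promoter windows (500 bp upstream to 0 bp, and 2000 bp upstream to 500 bp downstream), the share of protein-coding genes as expectation, genes matched on deciles of the upstream gap, reciprocal overlap, all relaxed peaks, windows of 25 and 100 bp around summits, single words and the TAAT core, unbound promoters, and distances of 10 and 50 kb at the transgene loci. The tests of small RNA genes, housekeeping and heat shock genes, the chromosome I region, the base shuffles of summit windows and the nearest-gene assignment were added after the data were seen.

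The planned tests, the small RNA test and the base shuffle test were checked on simulated peak sets of 545 peaks and the 19973 genes. In 20 sets placed at random, the chromosome test made 1 call and the promoter test made 2. The list tests, the matched list test, the small RNA test and the homeodomain word test made 0. These sets were uniform over the genome, without the promoter placement or base composition of the real summits. The matched list test was given simulated upstream gaps, so matching on the real gaps was not checked. The base shuffle, correlation and locus tests were run on planted sets only. All 25 planted ribosomal protein promoters were recovered, and the planted list, chromosome excess, promoter share, word, correlation and locus were each called. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.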

Results

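Chromatin immunoprecipitation followed by sequencing was used to map an eGFP-tagged CEH-30 protein on the genome of late embryos of the nematode Caenorhabditis elegans. CEH-30 is a BarH-type homeodomain transcription factor known for keeping the male-specific CEM neurons alive. Whole embryos of mixed sex from strain OP120, which carries an integrated ceh-30 transgene in an unc-119 mutant background, were used in 2 biological replicates that form 1 group. No group was set against another, so each comparison below is within the peak lists: where the peaks lay, which genes they lay beside, which sequence they held and how the replicates compared. The authors' optimal list, made by the IDR procedure, held 545 peaks on the ce11 assembly. These were the 545 pooled peaks of highest signal, and 538 of them overlapped a relaxed peak of both replicates. Each peak has a signal value given by the authors' peak caller, which ran from 38.9 to 792 with a median of 48.5 in this list. Relaxed lists, made before the IDR procedure, held 30000 peaks for replicate 1, 17926 for replicate 2 and 30000 for the pooled replicates. Read depth is unknown, since the lists give no read counts.

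The highest signal lay upstream of nhr-12, a nuclear hormone receptor gene. The peak at V:10084065-10084406 had its summit in intergenic sequence 183 bp upstream of the nhr-12 5′ end, with a pooled signal of 792, and it ranked 2 in replicate 1 and 1 in replicate 2. It also lay in the promoter window of R04B5.6. The next highest, at II:2221577-2221811, had a signal of 249 and lay in an intron of cbs-2, 1785 bp upstream of Y59C2A.3, the nearest protein-coding 5′ end. Ranks 3 to 5 lay close together on chromosome I, by Y48G10A.3 (signal 235, 1506 bp upstream), soem-1 (signal 188, 231 bp upstream, in an intron of ndx-8) and Y87G2A.25 (signal 187, 330 bp upstream). The peak at C02F5.12, at III:8242863-8243206, had its summit 6 bp upstream of the 5′ end and a signal of 172. A second nuclear receptor gene, nhr-87, held a peak with a signal of 167 in its own intron at IV:1624547-1624756.

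Ranks 8 to 15 had signals from 123 down to 107. They were nearest to F36A2.7, coa-5, eipr-1, ints-4, eelo-2, C04A11.5, eif-3.J and T02E1.2. The coa-5 peak lay 10157 bp downstream of that 5′ end, in an intron of pad-1. The ints-4 peak lay in the gene's 5′ UTR, the eipr-1 peak in a coding exon of Y87G2A.13 and the eif-3.J peak in the 3′ UTR of slc-25A46. The C04A11.5 peak lay 21 bp from a tRNA gene, and the T02E1.2 peak lay 47 bp from the snoRNA gene T02E1.9. Of the 15 peaks, 14 had most of their 32-base words within 50 bp of the summit at 1 place in the genome. The coa-5 peak had 61.4% of those words at more than 1 place. The eipr-1 peak ranked 5 in replicate 1 and 1576 in replicate 2.

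Chromosome I held more peaks than its length predicted, and chromosomes IV and V held fewer. Chromosome I had 134 of the 545 peaks, 24.6% (95% exact interval 21.03% to 28.4%), against 15.03% of the nuclear bases, a ratio of 1.64 (exact binomial test, adjusted p = 3.83e-08). Chromosome III had 95 peaks, 17.4% against 13.7% (exact test, adjusted p = 0.0227). Chromosome V had 76 peaks, 13.9% against 20.9% (exact test, adjusted p = 0.000112), and chromosome IV had 70, 12.8% against 17.4% (exact test, adjusted p = 0.00789). In the 272 peaks of highest signal neither chromosome III nor IV passed (exact tests, adjusted p = 0.0968 and p = 0.0617). Chromosome II, with 71 peaks, did not differ from its share of bases past the threshold (13.03% against 15.2%, exact test, adjusted p = 0.204).

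On chromosome I, 19 of the peaks lay between 13.4 and 13.8 Mb, a region picked after the data were seen, and 6 of these were among the 15 of highest signal. The densest 400 kb window anywhere on the chromosome held 22 peaks, against at most 14 in the densest window of 1000 sets placed at random on it (permutation p = 0.001, the smallest they can give, one-sided, adjusted p = 0.00599 over the 6 chromosomes). The densest windows of chromosomes III and V, with 11 and 8 peaks, also passed (permutation, adjusted p = 0.044 each). Random placement here ignores where genes lie.

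**Figure D1:**
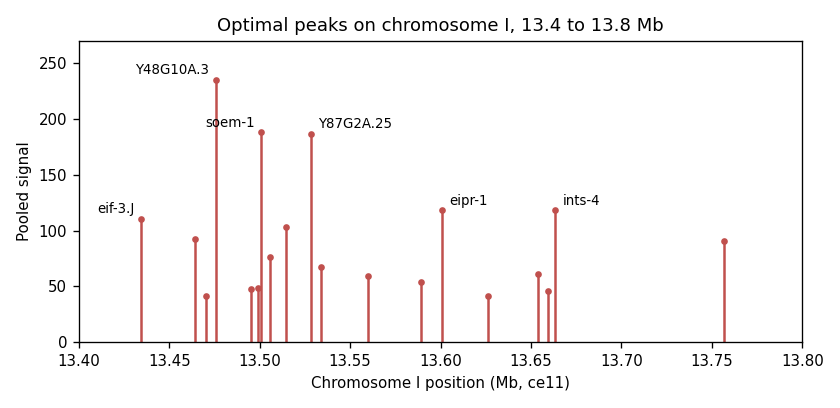
Optimal peaks on chromosome I from 13.4 to 13.8 Mb (ce11), each a line at its summit position (Mb) with its pooled signal as height and the nearest protein-coding gene named for the 6 of highest signal. The 19 peaks include those by Y48G10A.3, soem-1 and Y87G2A.25, with signals of 235, 188 and 187.

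The X chromosome, which carries ceh-30 and is present in different doses in the sexes, held 99 peaks, 18.2% (95% exact interval 15.02% to 21.7%) against 17.7% of bases (exact test, adjusted p = 0.736). Against its 13.7% share of protein-coding genes the same count was a 1.33-fold excess (exact test, adjusted p = 0.00662). In the 545 peaks of highest signal in replicate 1 alone the X share was 14.5%, below its share of bases (exact test, adjusted p = 0.0672), and in those of replicate 2 it was 17.98%. Peaks were treated as independent, and neighbouring peaks may not be. The adjustment was Benjamini-Hochberg over the 6 chromosomes.

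**Figure D2:**
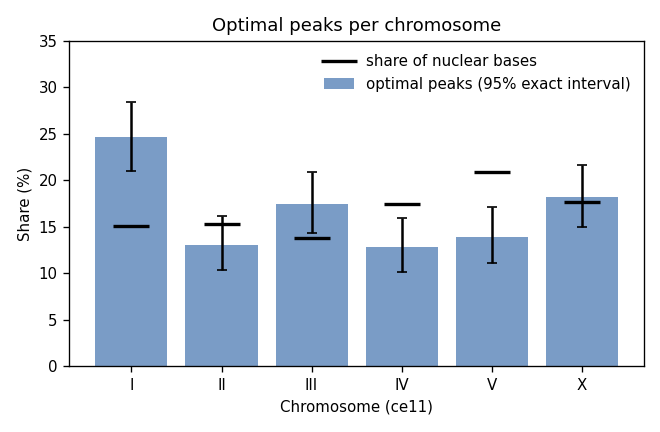
Share of the 545 optimal peaks on each chromosome (bars, %, with 95% exact binomial intervals) and share of the nuclear bases (black lines, %). Chromosome I stands above its share of bases at 24.6% against 15.03%, and chromosome V below it at 13.9% against 20.9%.

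Summits lay in front of genes. Of the 545 summits, 339 were in the window from 1000 bp upstream to 500 bp downstream of a protein-coding 5′ end, 62.2% (95% exact interval 58.0% to 66.3%) against 25.8% in shuffles within each chromosome, a ratio of 2.41 (permutation p = 0.002, the smallest that 1000 shuffles can give). Intergenic sequence within 1000 bp upstream of a gene held 287 summits, 52.7% against 11.9% in shuffles. Exons of protein-coding genes held 37 summits, 6.79% against 29.6%, and introns held 121, 22.2% against 34.4%. Each of these shares also had a permutation p of 0.002. The median distance from a summit to the nearest protein-coding 5′ end was 417 bp, and 400 summits lay upstream of it.

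Of 18 gene lists fixed before the data were examined, the ribosomal protein list was the only one past the threshold. Among 76 ribosomal protein genes, 25 had a summit in the promoter window, 32.9% (95% exact interval 22.5% to 44.6%) against 2.29% of the other 19897 protein-coding genes (Fisher's exact test, adjusted p = 8.1e-21 over the lists). The highest signals were 99.3 at rpl-20, at IV:4749907-4750250 and 301 bp upstream, and 97.96 at rpl-3, at III:3867405-3867748 and 277 bp upstream. Next came rps-28, at IV:1659070-1659413 with a signal of 94.3, and rps-20, at I:14469160-14469503 with 93.5. All 4 summits were intergenic. The rpl-20 and rps-20 summits also lay in the promoter windows of Y17G9B.5 and ekl-4, whose 5′ ends were nearer, at 161 and 168 bp against 301 and 229 bp, and the rps-28 summit also lay in that of Y41D4B.4. Against genes with a matched upstream gap the expected count was 3.01 (permutation p = 0.0002, the smallest that 10000 draws can give, adjusted p = 0.0036). With each summit given only to its nearest 5′ end, a choice made after the data were seen, 12 of the 76 genes remained, 15.8% against 1.62% of other genes (Fisher's exact test, adjusted p = 8.7e-08).

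None of the regulatory or cell type lists passed the test. Nuclear receptors had 7 bound genes of 274, 2.55%, close to the 2.4% of all protein-coding genes (Fisher's exact test, adjusted p = 1). After nhr-12 these were led by nhr-256 (signal 62.1), nhr-47 (61.7, summit in its 5′ UTR and also in the promoter window of dnj-19) and nhr-48 (52.8). The 32 basic helix-loop-helix genes had 1, hlh-2, which encodes the common dimerization partner of that family, 971 bp downstream of the summit at I:7194891, where no replicate 1 peak overlapped. Neuropeptide genes had 2 of 140, ins-39 (signal 59.5) and nlp-4 (44.9, also in the promoter window of exos-3). Ciliated sensory neuron genes had 1 of 33, daf-19, the RFX factor of cilium formation, with a signal of 56.6 at a summit 321 bp upstream. Body wall muscle genes had 1 of 19, unc-112, which encodes a muscle attachment protein, with a signal of 62.1.

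Collagen genes had 4 of 156, col-38, col-71, col-185 and col-85, with signals from 59.8 to 39.1. The col-38 and col-71 summits also lay in the promoter windows of the ribosomal protein gene rpl-5 and of Y49F6B.2, whose 5′ ends were nearer. The col-85 peak had 67.1% of its 32-base words within 50 bp of the summit at more than 1 place in the genome. Histone genes had 3 of 72, which stand under 50 names. The his-67 and his-68 genes shared 1 summit, also in the promoter window of alg-5, with a signal of 78.5, and his-37 had 47.0. Some named list members lay outside the 545 strongest peaks of 1 replicate. In replicate 2 the his-37 peak ranked 3727, nlp-4 1695, col-71 790, nhr-48 744 and col-85 614. In replicate 1 col-185 ranked 2610 and daf-19 774, and hlh-2 had no peak. The other named members ranked within the 545 strongest of both replicates. No promoter summit was found at the 78 homeobox genes, 18 sex determination genes, 19 cell death genes, 20 pan-neuronal genes, 8 glial genes, 22 epidermal genes, 15 intestinal genes, 13 pharyngeal genes, 21 germline genes or 31 major sperm protein genes. The 95% exact upper limit was 4.62% for the homeobox list and 36.9% for the glial list, so lists of this size cannot show a shortfall against 2.4%.

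**Figure D3:**
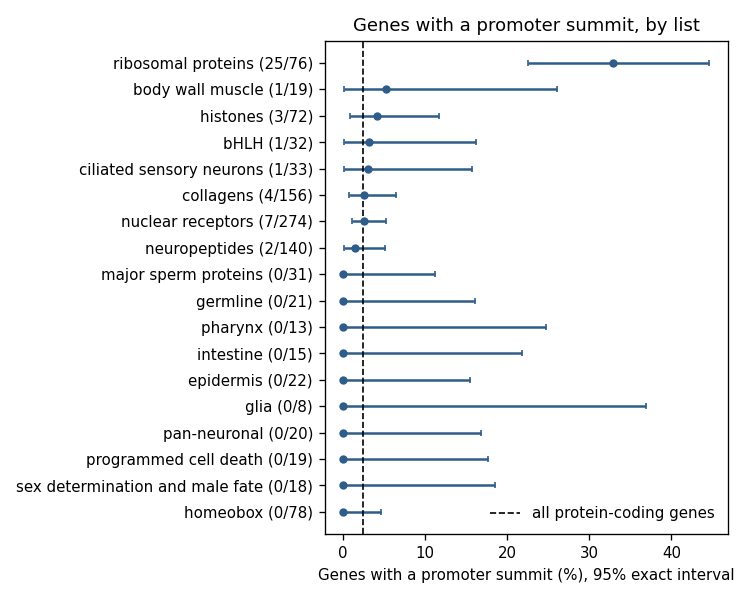
Percentage of genes with an optimal summit in the promoter window for each of the 18 lists (points, with 95% exact binomial intervals) and for all protein-coding genes (dashed line, 2.4%). Bound and total members stand beside each name. The ribosomal protein list lies at 32.9%, and the intervals of the homeobox and nuclear receptor lists include the line.

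The tagged gene, the cell death gene egl-1 and the transgene marker unc-119 had no optimal peak in their promoter windows. The nearest optimal summit to ceh-30 (X:3063574-3065551) was 27.4 kb upstream, and the pooled relaxed list had a peak 615 bp upstream of the gene with a signal of 10.8, ranked 26202 of 30000. At egl-1 (V:14431308-14432359), the gene whose product starts programmed cell death, the nearest optimal summit was 17.1 kb downstream of the 5′ end, and no relaxed list had a summit in the promoter window. The nearest pooled relaxed summit was 965 bp downstream of the egl-1 5′ end, with a signal of 10.8, ranked 26449 of 30000. At unc-119 (III:10902641-10908935) the nearest optimal summit was 53.6 kb upstream, and the pooled relaxed list had a peak 94 bp downstream of the 5′ end with a signal of 14.8, ranked 11355 of 30000. Within 20 kb of ceh-30 the relaxed lists held 9 summits in replicate 1, against a mean of 12.12 in random windows of the same length on X (permutation p = 0.803, one-sided), and 7 in replicate 2 against 7.32 (permutation p = 0.582). Within 20 kb of unc-119 they held 22 against 15.8 (permutation p = 0.129) and 11 against 9.56 (permutation p = 0.365).

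Homeodomain words were scarcer at summits than beside them. At least 1 of TAATTG, TAATTA and TAAACG, on either strand, stood within 50 bp of 43 summits, 7.89%, against 93 of the windows centred 300 bp to the left, 17.1%, and 94 of those to the right, 17.2% (exact McNemar tests, p = 8.27e-06 and p = 4e-06, two-sided). TAATTG was at 19 summits and TAATTA at 11, both below the flanks, while TAAACG, at 14, did not differ from either flank (exact McNemar tests, p = 0.143 and p = 0.487). The TAAT core was within 50 bp of 33.4% of summits against 65.3% and 64.8% of flanks (exact McNemar tests, p = 1.97e-25 and p = 1.21e-24). Summit windows had 48.04% G and C, and the flanks 36.2% and 35.4%, a difference that the comparison with flanks does not correct for. Among words of the same base composition, ordered by the ratio of summit to flank, TAATTG ranked 43 of 60, TAATTA 6 of 14 and TAAACG 57 of 120. Shuffling the bases within each summit window, a comparison added after the data were seen, gave a mean of 11.9% of windows with at least 1 of the 3 words, against the 7.89% observed (permutation p = 0.002, the smallest that the shuffles can give). Such shuffles keep base counts and not which bases adjoin, and the flanks were not shuffled. The shortfall against shuffles therefore cannot be tied to the summits.

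Of 2080 words of 6 bases, counted with their reverse complements, 439 were more frequent at summits and 317 less frequent past the threshold (Fisher's exact test, Benjamini-Hochberg). Summit and flanking windows of the same peak were treated as independent here, so the p-values ignore their pairing. The 5 higher words with the smallest p all hold CG, and summit windows are richer in G and C, which this comparison does not correct for. GACGCA was within 50 bp of 102 summits, 18.7%, against 2.48% of flanking windows (exact test, adjusted p = 1.12e-25). ACGCAG, which overlaps it, was at 17.1% against 2.29%. GCGCCA was at 14.1% against 1.28%, CGCGCA at 15.6% against 1.93% and GCGCAC at 14.9% against 1.65%. The words lower at summits with the smallest p were AAAAAT, at 18.7% against 47.2%, and TAAAAA, at 10.3% against 34.3%.

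**Figure D4:**
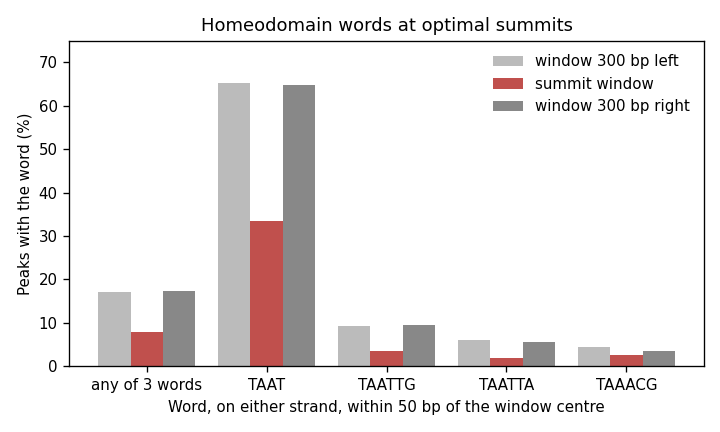
Percentage of the 545 optimal peaks with each homeodomain word within 50 bp of the summit (red) and of the centres of windows 300 bp to the left and right (grey). For the 3 words together the summit window lies at 7.89% against 17.1% and 17.2%, and for TAAT at 33.4% against 65.3% and 64.8%.

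The replicates shared many of their strongest peaks, and the rank correlation of their signals across the optimal peaks was low. Of the 545 replicate 1 peaks with the highest signal, 242 overlapped 1 of the 545 highest of replicate 2, 44.4%, where random replicate 2 peaks gave a mean of 15.9 and at most 26 in 100 draws. Of the optimal peaks, 237 were among the top 545 of both replicates, 122 of replicate 1 only, 145 of replicate 2 only and 41 of neither. Across the 538 optimal peaks with an overlapping peak in both replicates, Spearman's rho was 0.0393 (95% interval -0.0479 to 0.126, permutation p = 0.363) and Pearson's r of the log2 signal was 0.183 (permutation p = 6e-05). Across the 7296 pooled relaxed peaks found in both replicates, rho was 0.338 (95% interval 0.317 to 0.359, permutation p = 0.0001, the smallest that 10000 pairings can give). These are correlations across peaks, which are not independent replicates. The optimal peaks are also those of highest pooled signal. With replicate 2 values shuffled before 545 peaks were taken by summed signal, rho averaged -0.819. A rho of 0.0393 in the selected peaks therefore does not show that the replicates are unrelated.

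**Figure D5:**
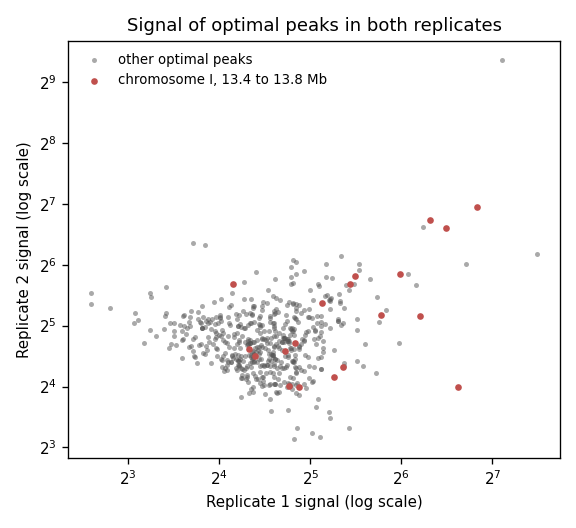
Replicate 1 signal against replicate 2 signal (both on log axes) for the 538 optimal peaks with an overlapping peak in both, with those on chromosome I from 13.4 to 13.8 Mb in red. The nhr-12 peak lies at the upper right at 138 and 661. Over the plotted peaks rho is 0.0393, a value that selection on the pooled signal can lower.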

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

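The excess on chromosome I, the promoter excess, the ribosomal protein list as the 1 list past the threshold and the lower share of homeodomain words kept their direction and side of the threshold under all alternatives run for them, except TAAACG alone, whose difference of -1.38 percentage points did not pass (exact test, p = 0.487). Over the alternatives, 195 results kept both and 22 changed direction, none of the 22 past the threshold before or after. Most of the 195 were gene lists that never passed, 10 of which had no bound member in the main setting. The count is therefore no measure of how robust the results that passed are. The promoter share ran from 50.1% to 71.4% over the windows and from 59.3% to 63.9% without either replicate. For the word test, single-replicate differences were -9.91 and -7.71 points. The nearest-gene assignment, the base shuffles of summit windows and the set without the chromosome I region were added after the data were seen.

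The X share, 18.2%, passed the threshold as a 1.33-fold excess when set against the share of protein-coding genes, which is the alternative's own construction, and fell to the other side of its expectation at 14.5% without replicate 2, against 17.98% without replicate 1. Chromosome II was at 16.15% without replicate 2, above its share of bases, and at 15.23% without replicate 1, and against gene shares its 13.03% passed the threshold. Chromosomes III, at 17.6%, and IV, at 12.5%, no longer passed with the 272 peaks of highest signal. The replicate rho rose to 0.338 over all pooled relaxed peaks. Within 50 kb of ceh-30 there were 2 optimal summits against a mean of 0.579 in random windows (permutation p = 0.106). Replicate 2 had 24 summits against 17.9 within 50 kb (permutation p = 0.149) and 6 against 3.81 within 10 kb (permutation p = 0.205). These counts moved above the random mean, and none passed the threshold.

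Lists that are not past the threshold changed sides of the background rate as few genes entered or left, or as the background itself moved. The basic helix-loop-helix list fell to 0% with the higher-signal peaks, without replicate 2 and in the short window. In the long window it was at 3.12%, nuclear receptors at 2.55%, ciliated neurons at 3.03%, cell death at 10.5% and germline at 4.76%. In the short window nuclear receptors were at 1.09% and collagens at 1.28%, the latter also with the nearest-gene assignment. Without either replicate nuclear receptors were at 1.82% and collagens at 1.92%, ciliated neurons were at 0% without replicate 2 and germline at 4.76% without replicate 1. The cause was not tested for any of these. Replicate correlation needs both replicates, so neither could be left out. No paired analysis was possible because there is a single group.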

Other observations

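The tests of small RNA genes, heat shock and housekeeping genes, the chromosome I region, replicate selection, nearest-gene assignment and words at the ribosomal and small RNA peaks were chosen after the data were seen. Genes for small structural RNAs lay by many summits. Within 200 bp of a tRNA gene there were 45 of the 545 optimal summits, 8.26% against 0.284% in shuffles within chromosomes, and by snoRNA genes, which guide RNA modification, there were 36, 6.61% against 0.202% (permutation, adjusted p = 0.0028 each). Without replicate 2, the tRNA count was 28, 5.14% (permutation, adjusted p = 0.00466). Small nuclear RNA genes had 6 summits and microRNA genes had 7, the latter 4 without replicate 2 (permutation, adjusted p = 0.0028 each with both replicates). The excess was not particular to these classes: other noncoding RNA genes, the annotation's ncRNA class, had 125 summits, 22.9% against 3.4% (permutation, adjusted p = 0.0028), and 17.99% against 3.22% with positions drawn only from promoter windows. Long intergenic RNA genes had 5, 0.917% against 0.315%, and did not pass (permutation, adjusted p = 0.0699). In the 272 peaks of highest signal they had 4, 1.47% against 0.357%, and passed (permutation, adjusted p = 0.032), while the other alternatives gave an adjusted p from 0.19 to 0.326. The summit at I:13463972, in an intron of ints-8, lay 17 bp from rpr-1, the RNA component of RNase P. Genes of piRNAs had 4 summits, 0.734% against 2.47% (permutation, adjusted p = 0.00466). With positions drawn only from promoter windows, tRNA, snoRNA and small nuclear RNA genes together still had 26 of 339 summits, 7.67% against 0.562% (permutation p = 0.002, the smallest that the shuffles can give). In those draws the microRNA and piRNA calls were lost (permutation, adjusted p = 0.157 and p = 0.47). Of the 87 summits by such genes, 8 were mostly in sequence found more than once in the genome, so their placement is uncertain.

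Heat shock and chaperone genes also had promoter summits, 7 of 30, 23.3% against 2.37% of other genes (Fisher's exact test, p = 5.59e-06). The 7 were hsp-1, hsp-3, hsp-110, dnj-13, dnj-19 and the divergent pair hsp-16.2 and hsp-16.41, which share 1 summit. That summit lay in a coding exon of hsp-16.41, 324 bp downstream of its 5′ end, and not between the 2 genes. Of the names on this list, 4 are also on the list of housekeeping genes. The dnj-19 summit is the one named for nhr-47, whose 5′ end is nearer, and the dnj-13 and hsp-110 summits also lay in the promoter windows of F54D5.9 and rpn-3. With each summit given only to its nearest 5′ end, 5 of the 30 genes remained, 16.7% against 1.65% (Fisher's exact test, p = 0.00013). The hsp-16 peak had a replicate 2 signal of 49.6, rank 39, and a replicate 1 signal of 10.7, rank 5153. Over the 6 peaks at these genes the log2 ratio of replicate 2 to replicate 1 had a median of 0.14 against 0.21 elsewhere (permutation p = 0.826).

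For the concentration of peaks at ribosomal protein and small RNA genes, the first pattern weighed, the share with a homeodomain word at the summit minus the mean of the flanks was -9.27 percentage points over all optimal peaks and -9.63 points over the 109 peaks of the pattern, but summits are richer in G and C than flanks, so these differences do not decide on binding through the words. Against base shuffles of the same windows the difference was -2.93 points over the 109 peaks and -3.02 over the 87 by small RNA genes (permutation p = 0.394 and p = 0.462). The upper 95% exact limits were 13.95% and 14.4% on shares of 10.3% and 9.91% in shuffles, which argues against an excess of 5 points or more over the shuffled shares. The shuffles keep base counts and not which bases adjoin, so the share to be met without binding may differ, and a smaller excess stays possible. For the 23 peaks in ribosomal protein promoters the difference was -2.70 with an upper limit of 28.04%, so an excess there cannot be told apart from none with so few peaks. Signal at highly transcribed genes in general may account for part of the pattern, the peaks at ribosomal protein genes. Transcription was not measured, and the evidence covers protein-coding genes only, not the small RNA genes. Of 64 housekeeping genes outside the ribosome, from a list written before it was tested, 23.4% had a promoter summit against 2.34% of other genes (Fisher's exact test, p = 2.25e-11). With each summit given only to its nearest 5′ end, the shares were 15.6% and 1.63% (Fisher's exact test, p = 1.05e-07). Recruitment of CEH-30 by other proteins at such genes, of which eef-2, eef-1A.1, tba-2, tbb-1, atp-1 and vha-8 were among the 15 in the first count, was not tested and stays open.

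The second pattern is a group of peaks near the right end of chromosome I, where 19 optimal peaks lay between 13.4 and 13.8 Mb. Of these, 6 were among the 15 of highest signal, and the same 6 were among the 8 optimal peaks narrower than 300 bp. Gene density is argued against, since the 59 protein-coding 5′ ends there lay at the 20.4th percentile of random windows, and so is repeated sequence, since 0% of the 19 peaks were mostly in words found more than once. A raised local background or copy number may contribute: relaxed peaks that overlap no optimal peak were 1.38 times the random mean in replicate 1 and 1.46 times in replicate 2 (permutation p = 0.0206 and p = 0.0253), where optimal peaks, whose density led to the choice of region, were 5.38 times theirs. The relaxed peaks come from the same libraries, so their p-values do not allow for the choice of region. The random windows also overlapped each other and the region. No biological explanation was tested. Without this region chromosome I kept 115 peaks, 21.9% against 15.03% (exact binomial test, adjusted p = 0.000185).

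The third pattern is the near-zero rank correlation of the replicates across optimal peaks. Selection on the pooled signal may lower it, since a peak weak in one replicate must be strong in the other to be listed. Over all relaxed peaks found in both replicates rho was 0.338. When replicate 2 values were shuffled before the 545 peaks with the highest summed signal were taken, rho averaged -0.819, and the same selection on the real pairs gave -0.0436 (permutation p = 0.001, the smallest that the shuffles can give). A low rho in the optimal list is consistent with such selection and does not by itself measure disagreement.

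Extra copies of ceh-30 and unc-119 in the transgene could raise peak counts there. Within 20 kb the lowest permutation p over both loci and both replicates was 0.129, at unc-119 in replicate 1. There, 15 summits against 8.97 lay within 10 kb (permutation p = 0.0621) and 49 against 36.3 within 50 kb (permutation p = 0.0697), which leans towards an excess. None of these passed the threshold, and a control from the same strain would remove an excess, so the question stays open.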
